A study of Mus musculus with 2 samples.

How the data were processed

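Total RNA of 2 mouse embryonic stem cell cultures, 1 labelled Mof wild type and 1 labelled Mof null, was measured on 1 array each. The authors deposited 1 table of 45101 probe sets with 1 log2 value per array, and per the submitters' processing notes the values were made with RMA in the affy package of R 2.10.0. RMA corrects the background, quantile-normalizes probe intensities across arrays and summarises the probes of each probe set by median polish. The log2 scale was taken from the values, which ran from 2.77 to 14.7 with medians near 6 on both arrays, and the sorted values of the arrays differed by at most 0.13. Whether other arrays were part of the same RMA run is not given in the sources used here, and scanner intensities and detection calls were not used here. Quantile normalization makes the arrays alike in distribution, so a change of most transcripts in the same direction cannot be seen in such values, and RMA compresses differences near the floor and near saturation. For arrays, their number limits the precision, and here it is 1 per genotype.

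Probe sets were named through the platform annotation supplied with the data. It listed 35890 probe sets, of which 34958 name 1 gene symbol and 932 name several, and 9211 probe sets were not listed and stayed unnamed here. The 34945 probe sets with 1 symbol and 1 Entrez gene ID that are not Affymetrix controls were used, and 34741 of these IDs were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed none of the symbols. Genes of the lists that were not found by symbol or by an unambiguous older symbol are not analysed here. A gene took the value of its probe set with the highest mean over both arrays, chosen without regard to the difference, which gave 18193 genes. A gene was called expressed when the higher of its 2 values reached 6.02, the median (percentile 50) of all values of both arrays, which left 12015 genes. The difference of a gene is its log2 value on the array labelled Mof null minus that on the array labelled wild type, and folds are 2 raised to its size.

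With 1 array per genotype no test was run. Genes were counted by a rule of size, an absolute log2 difference of at least 1 (2-fold). Each of 32 gene lists was summarised by the median difference of its expressed members and by the percentile of that median among 10000 random lists of the same size, drawn to match the members over 20 bins of mean level. These percentiles describe the 2 arrays and are not p-values, since genes are not replicates. The lists cover pluripotency, epiblast, germ line, embryonic lineages, feeder fibroblasts, signalling, stress, metabolism, cell cycle, chromatin and reference genes. They, the 2-fold rule and the rule for named genes were fixed before the data were examined. The named genes are Kat8 (Entrez gene 67773), the 10 expressed genes with the largest positive and the 10 with the largest negative difference whose expressed probe sets share a sign and that have a gene name of their own, Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42, and of each list the expressed members with the largest absolute difference, at most 4. Acta2, Adm, Bmi1, Bub1, Cdkn2a, Cldn6, Cldn7, Col1a2, Dazl, Eif2s3y, Epcam, Gata4, Gata6, Igfbp7, Lefty1, Lum, Mki67, Ogt, Phlda2, Slc2a1, Sox17, Vegfa and the genes named under the other observations fall outside that rule and were chosen after their values were seen. For the closing section, 5 further lists (second fibroblast, macrophage, second pluripotency, second hypoxia and second extraembryonic endoderm) were written before their values were examined, and 8 gene families were chosen after values had been seen.

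The counting and the list percentiles were tested on simulated differences for the 12015 expressed genes of this comparison with a noise SD of 0.3. All of 200 genes planted with a shift of 2 log2 units were recovered and 8 unchanged genes were called. Of 200 unshifted lists of 20 genes, 4.5% fell outside the central range between percentiles 2.5 and 97.5, as did all of 100 lists shifted by 0.5. The simulated differences were independent between genes and held no variation between cultures. These rates therefore check the calculation only and do not carry over to the 2 arrays. Alternatives planned in advance were the mean of all probe sets of a gene, leaving out probe sets with the suffix _s_at or _x_at, no filter on level, a filter at percentile 75, centring on the median gene, a lowess correction (span 0.3) of the difference on the mean level, quantile normalization of the table, thresholds of 1.5-fold and 4-fold, unmatched random lists and leaving out the most changed member of a list. A further alternative, differences taken relative to the median of the pluripotency list, was chosen after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Nothing was compared across replicates, and leaving out an array was not possible with 1 per genotype.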

Results

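Gene expression was measured once in each of 2 mouse embryonic stem cell cultures, 1 labelled wild type for Mof and 1 labelled Mof null. Embryonic stem cells are pluripotent cells grown from the early embryo, and Mof (gene symbol Kat8) encodes an acetyltransferase of histone H4. The lines came from C57BL/6 embryos at 3.5 days post coitum, were used at passage 15 to 18, and were grown on mouse embryonic fibroblast feeders with LIF before 2 passages without feeders. Biotin-labelled RNA of each culture was hybridised to 1 Affymetrix array, which gave 45101 probe set values per array as RMA values on a log2 scale. The values ran from 2.77 to 14.6 with a median of 6.02 on the array labelled wild type, and from 2.85 to 14.7 with a median of 6.01 on the array labelled Mof null. There was 1 array per genotype, so no difference below has a replicate error, a p-value or a test, and every count rests on a fixed rule of size. The only spread that could be measured was that between probe sets: in 5362 genes with several expressed probe sets, the differences of probe sets of the same gene had a pooled SD of 0.33 on the log2 scale. Probe sets of a gene can read different transcripts, so this spread is not purely technical, and it holds no variation between cultures of a genotype. The 3' control probe set exceeded the 5' control probe set by 0.15 and 0.061 log2 units for GAPDH on the arrays labelled wild type and Mof null, and by 0.38 and 0.65 for beta-actin, all near the top of the scale, where differences are compressed. For the transferrin receptor, which was not near the top, it did so by 1.86 and 1.80. The 5' probe set of that transcript, at 4.53 and 5.35, lay below the level filter. Of 18 hybridization control probe sets 5 were above the level filter, of which the 4 for the cre control were 0.41 to 0.52 log2 units higher on the array labelled Mof null and the remaining one, AFFX-BioDn-3_at, was 0.16 higher.

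The targeted transcript itself did not separate the arrays in the labelled direction. Kat8 (Entrez gene 67773) was read by 1 probe set that names it alone, with a value of 8.06 on the array labelled wild type and 8.37 on the array labelled Mof null. The difference of 0.31 log2 units, or 1.24-fold higher on the array labelled Mof null, was smaller than the spread between probe sets of a gene. It was -0.29 relative to the median of the pluripotency genes, a scaling chosen after seeing the data that lowers every gene by the same amount. Where this probe set lies relative to the deleted part of the gene was not given in the sources used here, so its value does not check the labels. For this reason the arrays are named by their labels throughout, and every direction given below depends on those labels being right.

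More genes were at least 2-fold lower than at least 2-fold higher on the array labelled Mof null. Here and below a gene is counted by its brightest probe set, and other probe sets of a counted gene can lie on the other side of 2-fold. Of 12015 expressed genes, 1429 were at least 2-fold lower and 611 at least 2-fold higher, together 17.0% of the expressed genes. At 4-fold, 389 genes were lower and 35 higher. With differences taken relative to the median of the pluripotency genes described below, a scaling chosen after seeing the data, 2928 genes were at least 2-fold lower and 91 higher. Of the genes past 2-fold, 3.01% were then higher, against 29.95% as deposited. This scaling subtracts the same amount from every gene, so more lower and fewer higher genes follow by construction. The genes with the largest positive differences were Clic6, a chloride intracellular channel gene, at 9.69-fold, Amn at 8.65-fold, and the transcriptional coactivator Cited1 and the hypoxia-induced gene Ankrd37, each at 6.74-fold. They were followed by Lgals2, a galectin, at 6.67-fold, Irs4 at 6.58-fold, Cubn at 6.34-fold, the carbonic anhydrase gene Car4 at 6.29-fold, Podxl at 6.21-fold and the homeobox gene Crxos at 6.10-fold. Amn and Cubn encode the parts of an endocytic receptor of absorptive epithelia and visceral endoderm. The genes with the largest negative differences were Bcl2l15 at 14.4-fold, the smooth muscle actin gene Actg2 at 11.9-fold, the interferon-induced gene Ifit1 at 11.1-fold, the serotonin receptor gene Htr1b at 10.6-fold and Vgll3 at 10.5-fold. Parp3 was lower by 9.62-fold, the urokinase gene Plau by 9.56-fold, Oasl2 by 9.35-fold, Hoxc10 by 9.28-fold and Usp18, which removes the interferon-induced modifier ISG15, by 9.14-fold. Probe sets of a gene disagreed on size for Htr1b, where another expressed probe set differed by -0.099 log2 units, for Parp3 (-0.72 at the least), Plau (-1.72), Clic6 (1.29), Lgals2 (1.68) and Podxl (0.95). Among genes named below as past 2-fold, Epcam, Fancd2, Hoxc6, Hspa1b, Nr5a2, Ulk2 and Zfp352 also had an expressed probe set under 2-fold, with differences of -0.051, 0.77, -0.075, -0.79, 0.78, -0.50 and -0.81. Of the 806 genes past 2-fold that had several expressed probe sets, 365 had a probe set under 2-fold and 56 had a probe set of opposite sign. The median expressed gene was 0.10 log2 units higher on the array labelled Mof null and 56.7% of expressed genes were higher (95% Wilson interval 55.8 to 57.6%, over genes, which are not replicates), a share that was 47.4% after correction of a trend with level.

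**Figure D1:**
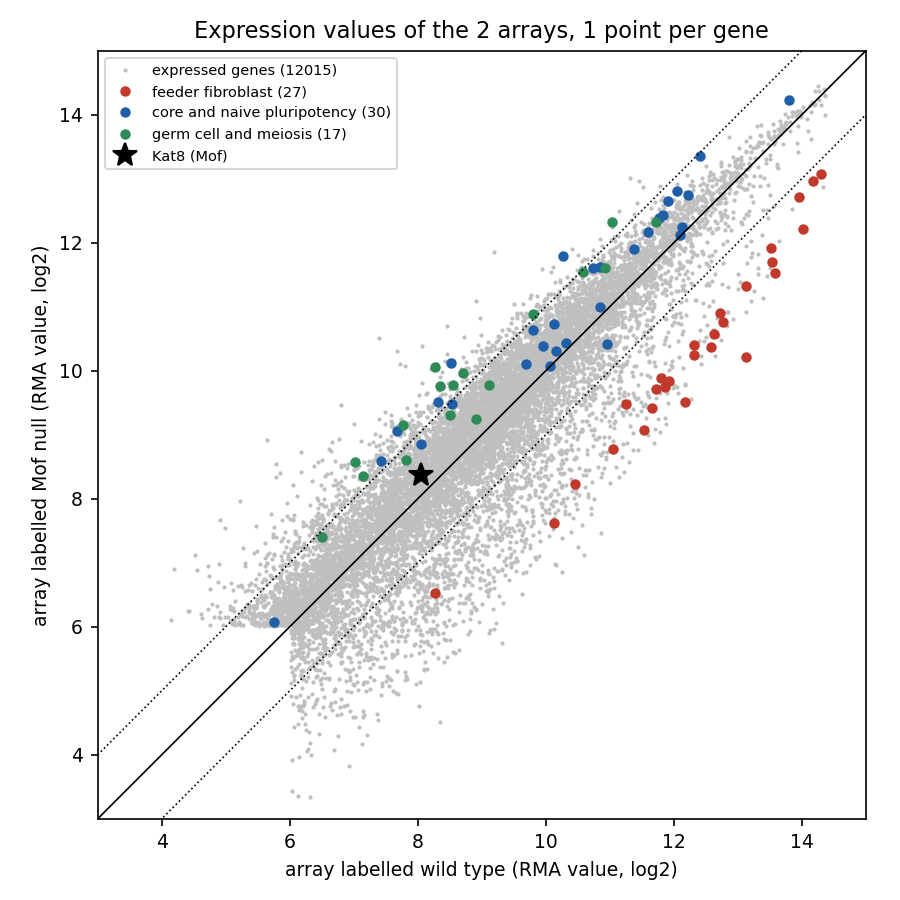
RMA values (log2) of 12015 expressed genes on the array labelled wild type (horizontal axis) and on the array labelled Mof null (vertical axis), 1 point per gene, with the solid line at equal values and dotted lines at a 2-fold difference. All 27 fibroblast genes (red) lie below the lower dotted line, 29 of 30 pluripotency genes (blue) and all 17 germ cell genes (green) lie above the line of equality, and Kat8 (star) lies 0.31 above it.

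Genes of the pluripotency network were modestly higher on the array labelled Mof null. Of 30 expressed genes of core and naive pluripotency, 29 were higher, 5 of them at least 2-fold, and none was 2-fold lower. The core transcription factor genes Pou5f1, Sox2 and Nanog were higher by 1.44-fold, 1.69-fold and 1.67-fold, from values of 12.2, 12.05 and 11.9 on the array labelled wild type. Zfp42 was higher by 1.43-fold and Esrrb by 1.51-fold, and the 3 expressed Esrrb probe sets lay between 0.54 and 0.71 log2 units. Klf4 differed by 0.025 log2 units, which turned negative under centring on the median gene, trend correction and quantile normalization. The largest differences in the list were those of Tcl1 (3.02-fold), the growth factor gene Fgf4 (2.87-fold), Dppa3 (2.61-fold) and Nr5a2 (2.30-fold). The median difference of the list was 0.60 log2 units (SD over genes 0.48, n = 30 genes), at percentile 99.99 of 10000 random lists matched on expression level, whose medians lay between -0.08 and 0.30. On the same pair of arrays the fibroblast marker list described below had a median of -2.0 and a macrophage list one of -2.14.

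Germ cell genes were higher as a group, and epiblast genes went both ways. All 17 expressed germ cell and meiosis genes were higher, 9 of them at least 2-fold, with Mael at 3.47-fold, the cohesin gene Smc1b at 2.95-fold and the synaptonemal complex gene Sycp3 at 2.67-fold, while Dazl was higher by 1.52-fold. The list median was 1.09 (SD 0.39, n = 17 genes) and lay above all 10000 random lists, while on the same arrays the medians of the fibroblast and macrophage lists were -2.0 and -2.14. Of 14 expressed formative and primed epiblast genes, 7 were at least 2-fold higher and 4 at least 2-fold lower. Otx2 was higher by 5.87-fold, Zic2 by 3.13-fold and Lef1 by 3.08-fold, whereas the N-cadherin gene Cdh2, which fibroblasts also express, was lower by 5.33-fold. The epiblast list median was 1.02 and lay above all random lists, but its mean was 0.44 with an SD over genes of 1.45. Among genes of the LIF, Nodal, BMP and Wnt pathways, the Nodal targets Lefty2 and Lefty1 were higher by 3.82-fold and 2.55-fold and the BMP target Id3 was lower by 4.07-fold. That list of 24 genes had 4 members at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.32 at percentile 95.08, which became 98.96 when Id3, its most changed member, was left out.

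Markers of fibroblasts, the feeder cell type of these cultures, had the median farthest from 0 among the 32 lists. Each of the 27 expressed fibroblast genes was at least 2-fold lower on the array labelled Mof null on its brightest probe set, while another probe set of Igfbp7 differed by 0.058 log2 units. The collagen gene Col1a1 was lower by 7.57-fold, from 13.1 to 10.2 (a second probe set differed by -1.77 log2 units), S100a4 by 6.33-fold, the transcription factor gene Twist2 by 5.70-fold, and Lum and Acta2 by 3.76-fold and 3.51-fold. The smallest difference was that of Col1a2, lower by 2.30-fold from a value of 14.2. All 27 genes were still above the expression threshold of 6.02 on the array labelled Mof null. The list median was -2.0 (SD 0.40, n = 27 genes), below all 10000 random lists.

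Several gene groups moved with the fibroblast markers. Of 34 expressed adhesion and cytoskeleton genes, 19 were at least 2-fold lower, with calponin Cnn1 at 6.89-fold and the myosin light chain gene Myl9 at 6.64-fold, and 5 were at least 2-fold higher, all of them epithelial or basement membrane genes such as the claudins Cldn6 (4.68-fold) and Cldn7 (4.48-fold) and Epcam (2.81-fold). The list median was -1.16. Of 19 expressed Hox cluster genes, which mark position along the body axis, 11 were at least 2-fold lower, 1 was 2-fold higher, and the list median was -1.58. Hoxc10 was lower by 9.28-fold and Hoxc8 by 7.5-fold, while Hoxc6 was lower by 5.18-fold on its brightest probe set and differed by -0.075 log2 units on another. Of 20 interferon response and antigen presentation genes, 13 were at least 2-fold lower and none was 2-fold higher. Ifit1, Oasl2 and Ifit3 were lower by 11.1-fold, 9.35-fold and 6.49-fold, and the list median was -1.23. Among 22 imprinted genes, 7 were at least 2-fold lower, led by Dlk1 (5.12-fold) and the fetal growth factor gene Igf2 (4.01-fold), and 2 were at least 2-fold higher, with Phlda2 at 3.0-fold, for a median of -0.65. The medians of these 4 lists lay below all 10000 random lists, and on the same arrays the fibroblast list median was -2.0 and that of 18 macrophage genes -2.14.

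Part of the endoderm genes were higher on the array labelled Mof null, while other lineage lists lay lower or did not stand apart. Of 22 expressed genes of primitive and definitive endoderm, 10 were at least 2-fold higher and none 2-fold lower, while 7 lay below 0. Besides Amn and Cubn, these included the laminin gene Lama1 (3.13-fold), the proteoglycan gene Srgn (2.86-fold) and the transcription factor genes Sox17 (2.69-fold) and Gata4 (2.5-fold), whereas Gata6 was higher by 1.09-fold. The list median was 0.70 (SD 1.06, n = 22 genes), above all random lists, but it was 0.11 at percentile 47.8 under a stricter expression filter. Of 13 expressed neural genes, 4 were at least 2-fold lower, led by Zic1 (7.72-fold) and Fabp7 (5.71-fold). Another 2 were at least 2-fold higher, including Pax6 (2.30-fold), and the list median of -0.24 lay at percentile 10.045. Of 11 expressed primitive streak and mesoderm genes, 4 were at least 2-fold lower, including the mesenchymal regulators Snai2 (4.81-fold) and Twist1 (4.48-fold), and the median was -0.40 at percentile 5.63, or -1.53 at percentile 0.99 under the stricter filter. Trophoblast genes did not stand apart, with 2 of 13 at least 2-fold higher, 2 at least 2-fold lower including Krt7 (3.60-fold), and a median of 0.27 at percentile 82.1. Of 6 expressed genes of the 2-cell-stage-like state, 3 were at least 2-fold lower, namely Tcstv1 (4.03-fold), Arg2 (2.78-fold) and Zfp352 (2.16-fold). That median of -0.89 lay at percentile 1.06, and at 4.41 without Tcstv1. On the same arrays the medians of the fibroblast and macrophage lists were -2.0 and -2.14.

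Several hypoxia-induced genes were higher on the array labelled Mof null. Of 22 expressed genes of glycolysis and hypoxia, 8 were at least 2-fold higher and none 2-fold lower. The targets of hypoxia signalling Ankrd37, Bnip3 and Egln3 were higher by 6.74-fold, 4.51-fold and 4.28-fold, the aldolase gene Aldoc by 4.32-fold and the glucose transporter gene Slc2a1 by 2.53-fold, whereas Vegfa differed by 0.22 and Adm by -0.65 log2 units. The median of the list was 0.41 (SD 0.92, n = 22 genes) at percentile 99.6, below the pluripotency list's 0.60, and on the same arrays the fibroblast and macrophage medians were -2.0 and -2.14. Oxidative phosphorylation genes had no member past 2-fold among 30, with a median of 0.17 at percentile 79.1. Cholesterol biosynthesis genes had 1 of 20 at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.19 at percentile 66.5. Genes of the unfolded protein and amino acid stress response had none of 25 past 2-fold, and their median of 0.39 lay at percentile 99.7, or 95.9 without probe sets that can match several genes. Heat shock genes had a median of 0.10 at percentile 46.6, which turned negative after centring and trend correction, with Bag3, Hspa1a and Hspa1b as the 3 of 12 that were at least 2-fold lower.

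Most cell cycle and DNA repair genes were higher, while most p53 target, immediate early and autophagy genes were lower. Of 34 expressed cell cycle genes, 26 were higher, 3 of them at least 2-fold, including the proliferation marker Mki67 (2.22-fold) and the mitotic checkpoint gene Bub1 (2.07-fold). The 5 genes at least 2-fold lower were Cdk6 (5.20-fold), the cyclin genes Ccnd2 (4.31-fold) and Ccnd1 (3.47-fold), and the cell cycle inhibitor genes Cdkn2b (5.01-fold) and Cdkn2a (2.77-fold). The list median was 0.56, above all random lists, and its mean 0.18. DNA damage response and repair genes had a median of 0.59 at percentile 99.98, with 19 of 22 higher and Fancd2 (2.54-fold) and Fanca (2.5-fold) leading. Of 22 p53 target and apoptosis genes, 7 were at least 2-fold lower and none was 2-fold higher, with Casp8 at 5.01-fold, Perp at 3.73-fold and the cell cycle inhibitor Cdkn1a at 3.31-fold, for a median of -0.48 at percentile 0.010. Of 17 immediate early genes, 5 were at least 2-fold lower, led by Jun (6.26-fold), Fosl1 (5.72-fold) and Egr1 (4.53-fold), and the median was -0.37 at percentile 0.90. Autophagy and lysosome genes had 6 of 24 at least 2-fold lower and none at least 2-fold higher, while 4 lay above 0, with Ulk2 at 2.66-fold, Lamp2 at 2.55-fold and Gabarapl1 at 2.35-fold, for a median of -0.47 at percentile 0.020. The fibroblast and macrophage list medians of -2.0 and -2.14 apply to the same arrays.

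Few chromatin regulators passed 2-fold. None of the 13 subunits of the MSL and NSL complexes, which contain Mof, was past 2-fold on its brightest probe set, while Phf20l1 and Ogt each passed it on another, with differences of -1.20 and -1.51. The largest differences among them were those of Wdr5, higher by 1.85-fold, and Phf20l1, lower by 1.71-fold with probe sets from -1.20 to 0.17, and the list median was 0.29 at percentile 84.7. None of 19 other histone acetyltransferase genes and partners and none of 14 histone deacetylase genes passed 2-fold, with medians of 0.26 and 0.15 at percentiles 83.4 and 60.6, the latter turning negative after trend correction. Of 27 polycomb and H3K4 methyltransferase subunits, Phc2 was lower by 2.08-fold and no other passed 2-fold on its brightest probe set, though Suz12 (up to 1.12) and Bmi1 (down to -1.05) did on another, while the median of 0.38 lay at percentile 99.3, with Ezh2 higher by 1.82-fold and Cbx7 by 1.97-fold, on arrays where the fibroblast and macrophage medians were -2.0 and -2.14. The 5 expressed histone genes of the replication-dependent list, which also holds variant histones, had a median of 0.23 at percentile 68.1. Among housekeeping groups, 24 ribosomal protein genes had a median of 0.076 (SD 0.11) at percentile 30.97 and 14 reference genes a median of 0.045 (SD 0.60) at percentile 26.6, both of which turned negative after centring and trend correction. Of the reference genes, 1 was at least 2-fold higher, Tfrc, and 2 were at least 2-fold lower, B2m and Gusb. Tfrc and Gusb also had an expressed probe set under 2-fold (0.83 and -0.74). No ribosomal protein gene passed 2-fold. Most of the ribosomal protein genes lay near the top of the scale, where differences are compressed. Y-linked genes were read on both arrays, with Eif2s3y at 9.70 and 9.85 and Kdm5d at 8.44 and 8.69 on the arrays labelled wild type and Mof null, and the list of Y-linked genes with Xist had a median of 0.25 at percentile 66.1. Across the 32 lists, 9 medians lay below and 9 above the central 95% of random lists, and 14 lay within it. Relative to the pluripotency list median, every positive median under 0.60 turns negative by construction, and 5 of the 9 above the random range did, those of the cell cycle, DNA repair, glycolysis and hypoxia, unfolded protein response, and polycomb and H3K4 methyltransferase lists.

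**Figure D2:**
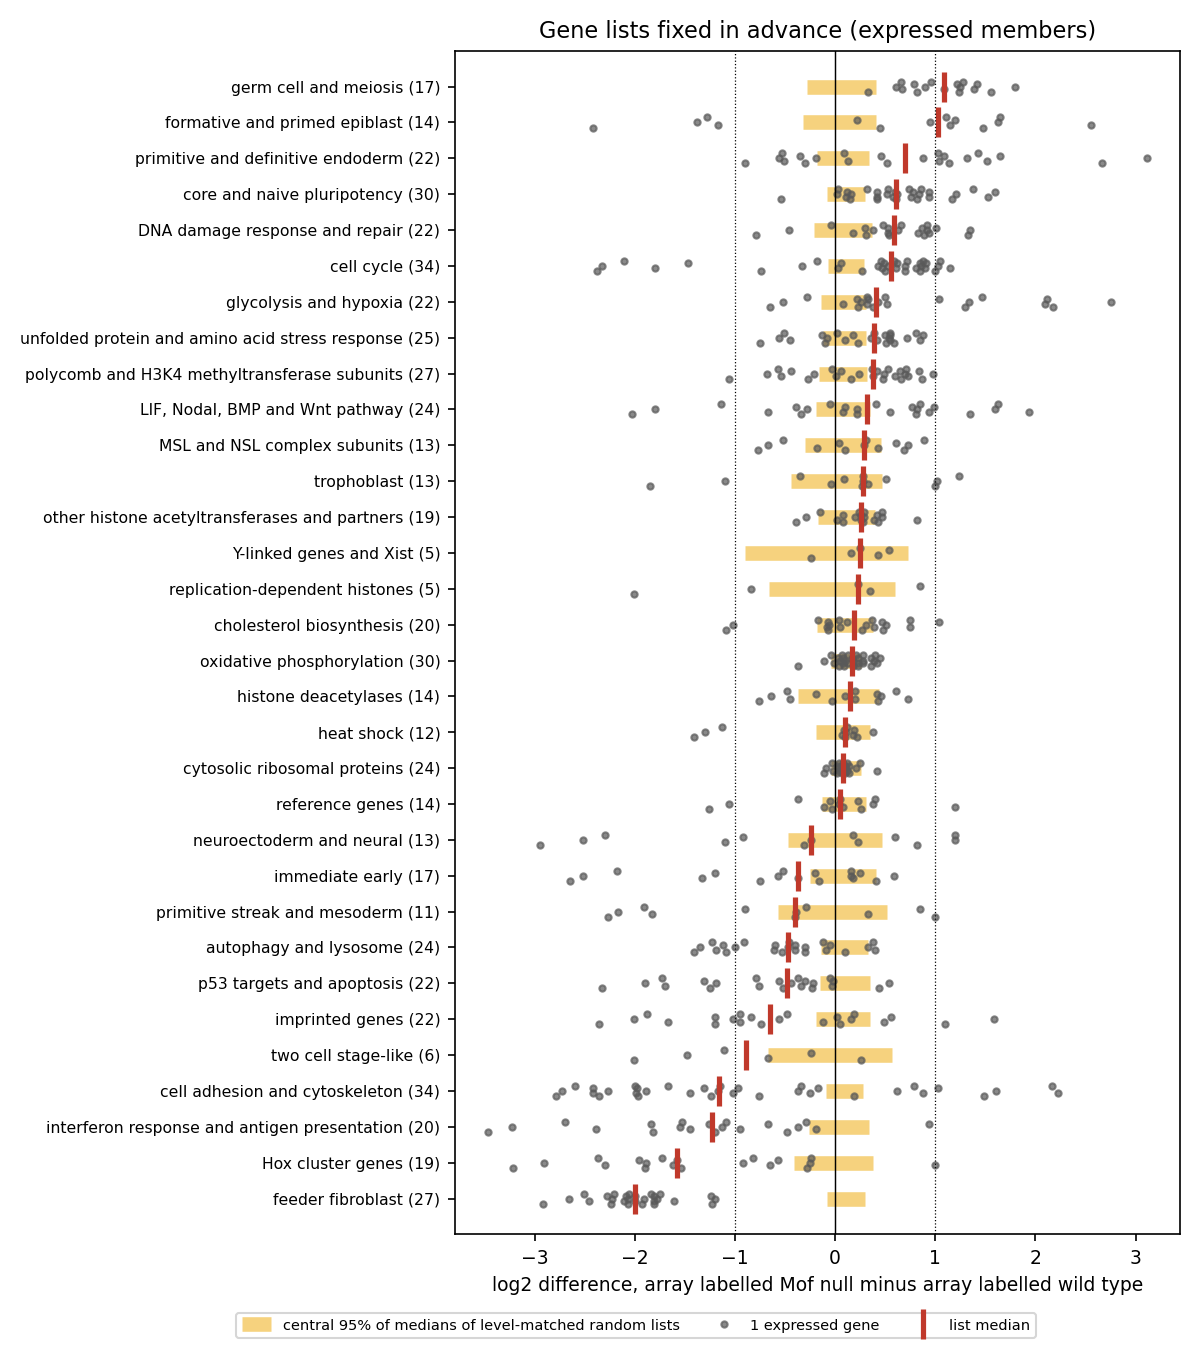
Log2 differences, array labelled Mof null minus array labelled wild type (horizontal axis), for the expressed members of 32 gene lists (rows, with the number of genes). Grey points are genes, red bars are list medians and yellow bands span the central 95% of the medians of 10000 level-matched random lists. The medians run from -2.0 for fibroblast genes to 1.09 for germ cell genes.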

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

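The counts of 611 genes at least 2-fold higher and 1429 at least 2-fold lower changed by over 1.5 times under 4 settings. They were 347 and 926 with the level filter at percentile 75, which tests fewer genes, 2084 and 2303 at 1.5-fold, 35 and 389 at 4-fold, and 91 and 2928 relative to the pluripotency list median, a setting chosen after seeing the data. Under that last setting 3.01% of the genes past 2-fold were higher, against 29.95% as deposited. It subtracts the same amount from every gene, so a fall of this share, and of every value given relative to the pluripotency list, follows by construction. The share of expressed genes higher on the array labelled Mof null, 56.7% as deposited, was 57.9% with mean probe sets, 59.96% without a filter, 57.6% at percentile 75, 58.5% after quantile normalization, 47.4% after trend correction, 49.996% after median centring, which fixes it, and 16.6% relative to the pluripotency list. The pluripotency list median of 0.60 was 0.44 after trend correction and 0.50 after centring. The fibroblast list median of -2.0 was -2.17 and -2.11 under the same settings and -2.60 relative to the pluripotency list. The Kat8 difference of 0.31 was 0.20 after trend correction, 0.21 after centring, 0.39 after quantile normalization and -0.29 relative to the pluripotency list, and it has no value without _s_at probe sets, since its only probe set is of that kind, nor with the filter at percentile 75, which it does not reach. The cause of shifts under trend correction was not tested. Relative to the pluripotency list, 5 medians above the random range turned negative by construction, namely polycomb and H3K4 methyltransferase subunits (-0.22), cell cycle (-0.046), DNA damage response and repair (-0.017), glycolysis and hypoxia (-0.20) and unfolded protein and amino acid stress response (-0.21). All 32 lists kept their side of the central random range with mean probe sets, without a filter, after trend correction, quantile normalization and centring, and with unmatched random lists, and the lists that changed side under other settings are given with their values in the report. The 2-cell-stage-like list has no value with the filter at percentile 75. Among the named genes other than Kat8, 26 moved by more than 0.33 log2 units with mean probe sets and 4 without _s_at and _x_at probe sets, and none of the named genes past 2-fold changed sign under the planned settings. Leaving out a replicate was not possible with 1 array per genotype. No paired analysis was possible because each genotype has 1 array. Values near the level filter are the least reliable, since no detection calls were used.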

Other observations

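The label-exchange and genotype tests and the 8 gene families were chosen only after the results were seen, and so were the reading that a second list of the same class cannot decide with 1 array per genotype, the margin of 1 SD of random lists used for the second hypoxia list and the recount of the second endoderm list by other probe sets.

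Beyond the lists of the report, macrophage genes were lower on the array labelled Mof null. Of 18 expressed macrophage markers, 17 were at least 2-fold lower, with the leukocyte phosphatase gene Ptprc at 6.80-fold, the adaptor gene Tyrobp at 5.16-fold and the lysozyme gene Lyz2 at 4.42-fold, from a value of 12.8, while Laptm5 differed by -0.13 log2 units. All 8 expressed annexin genes were lower, 6 of them at least 2-fold, with Anxa3 at 6.04-fold and a family median of -1.95, below all random lists. Among 17 expressed semaphorin genes, 6 were at least 2-fold lower, led by Sema3c at 7.65-fold, and 2 were at least 2-fold higher, with Sema4d at 2.89-fold on its brightest probe set and 0.51 log2 units on another. Of 8 expressed Wnt ligand genes, 3 were at least 2-fold lower, with Wnt5a at 7.86-fold and Wnt9a at 6.29-fold, none was 2-fold higher, and 4 lay above 0. The semaphorin and Wnt medians were -0.13 and 0.082, at percentiles 14.8 and 52, inside the central range of random lists. Of 7 expressed caspase genes, 3 were at least 2-fold lower, with a median of -0.20 at percentile 22.1, also inside that range. Of 6 glucose transporter genes of family 2, 1 was at least 2-fold higher on its brightest probe set, with a median of 0.34 at percentile 87.2. Slc2a3, at 0.52 on its brightest probe set, passed 2-fold on 3 of its 4 expressed probe sets, up to 1.79. Of 6 expressed claudin genes 2 were at least 2-fold higher, with a median of 0.60 at percentile 97.4, just inside that range. The 4 Rhox homeobox genes were all higher with a median of 0.70 at percentile 98.41. Only 1 protocadherin beta gene, Pcdhb17, was expressed, and it was lower by 7.82-fold.

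The first pattern is the lower level of all 27 fibroblast genes on the array labelled Mof null. The list median was -2.17 after the level trend was removed. As deposited, the list median was -2.0 and the central range of random lists matched to it on level ran from -0.078 to 0.30. With and without the removal, the list median lay below all 10000 random lists. These values argue against a dependence on expression level for this list. Other effects of normalization were not tested, because the correction removes only the average dependence on level. A candidate explanation is more feeder-derived RNA in the culture labelled wild type, since macrophages, which feeder preparations can hold, gave a list median of -2.14, beside the fibroblast median of -2.0. In a second fibroblast list, 84% of 25 expressed genes were at least 2-fold lower and the median was -1.62, with Bgn lower by 3.05-fold from 13.6, Serpinh1 lower by 1.63-fold from 13.1, and Nid2 and Plod2 higher by 1.88-fold and 1.11-fold. The macrophage median and the 84% share each met the bound set beforehand for RNA of that cell type in the culture labelled wild type. The labels describe 2 passages without feeders, which should remove feeder cells. Yet all 27 fibroblast genes were above the level filter on both arrays. Col1a1, the most changed of them, was at 10.2 on the array labelled Mof null. A loss of mesenchymal expression that follows the genotype would lower the second list too. For the fibroblast genes it cannot be told apart with 1 array per genotype. Such a loss alone would not account for the macrophage genes, of which 17 of 18 were at least 2-fold lower.

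The second pattern is the modest increase of pluripotency genes on the array labelled Mof null. A second pluripotency list of 20 expressed genes had 19 members higher and a median of 0.80 beside the first list's 0.60, which both dilution of stem cell RNA by other cells in the culture labelled wild type and an increase that follows the genotype would give, so they cannot be told apart with 1 array per genotype. If dilution alone set the first median, the stem cell share of the RNA on the array labelled wild type would be 65.8% of that on the array labelled Mof null. Members lay on both sides of that amount, from Tcl1 and Fgf4, higher by 3.02-fold and 2.87-fold, to Klf2, Klf4, Dppa2 and Nr0b1, with differences of 0.018, 0.025, 0.11 and 0.15, and Stat3 with -0.54. An exchange of the labels stays open, because Kat8 differed by only 0.31 log2 units and its probe set is not placed relative to the deletion.

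The third pattern is the set of hypoxia-associated and endoderm genes that were higher on the array labelled Mof null. Lower oxygen supply or denser growth in the culture labelled Mof null was tested on a second hypoxia list of 19 expressed genes. Of these, 15 were higher, 1 of them, Slc16a3, at least 2-fold. The list's median of 0.52 lay at percentile 99.69 of random lists matched on level. It lay below the pluripotency median of 0.60, the bound set beforehand for arguing against this explanation. The gap was less than the SD of random list medians, 0.16, a margin applied only after the value was seen, so the explanation stays open. More extraembryonic endoderm cells were tested on a second endoderm list, of which 40% of 15 expressed genes were at least 2-fold higher, including Spink1 (3.61-fold) and Rbp4 (3.25-fold), while Maf and Fst were lower by 5.48-fold and 3.85-fold, and the list median was 0.84. That share missed the 50% set beforehand for this explanation. The bound set beforehand for arguing against it, a list median at or below the pluripotency median of 0.60, was not met either, so the explanation stays open. Apom and Emb passed 2-fold on another probe set (1.84 and 1.04), which would bring the share past 50%, but this recount was made only after the values were seen. An effect of the genotype was not tested apart from either explanation.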
